A study of Mus musculus with 79 samples.

How the data were processed

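Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts and in punches of the suprachiasmatic nucleus (SCN). Per the labels' protocols, fibroblast RNA was extracted with TRIzol and made into libraries with the TruSeq RNA v2 kit, after a 1 h pulse of 100 nM dexamethasone, a glucocorticoid that sets cultured cells to a common circadian time. Per the labels' protocols, SCN RNA came from punches of mice aged 10 weeks, was extracted with RNeasy Micro columns and was made into libraries with the SMARTer Stranded total RNA pico v2 kit. The submitters' processing notes list bcl2fastq 2.18.0.12, Trimmomatic 0.36, TopHat2 2.1.1, Cufflinks 2.2.1 and the mm10 genome. The annotation and strand setting behind the values are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and members of near-identical families such as ribosomal proteins, major histocompatibility genes and U6 or 4.5S RNAs are uncertain.

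The deposited values were read as TPM (transcripts scaled to a common library sum) in the WT and KO fibroblast tables, a unit inferred from library sums between 970075 and 980677, and as FPKM (fragments scaled by gene length and library size) in the other tables. The deposited FPKM sum to between 258374 and 366414 in the DMSO and DZnep fibroblast libraries and to between 250552 and 322464 in the SCN libraries. The test design had assumed FPKM throughout. The same test on a log scale was used for TPM. Read depth is unknown, so no counting interval is given, and an exact 0 may be a failed estimate. Very short genes such as microRNA and small nucleolar RNA genes take extreme values in these units. Gene names that occurred more than once in an SCN table were averaged. Most SCN values have decimals that look like those of means of 4 numbers, and how they were made is not known, so what an SCN library value and its SD stand for is uncertain. Each arm was deposited as a separate table, so every comparison between arms sets tables made separately beside each other.

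Within each experiment, libraries were rescaled jointly by the median ratio to the geometric mean over genes at 1 or more in every library. Genes at 1 or more in at least 3 libraries were tested. Values were analysed as log2(value + 1), so fold changes of low genes are understated, with limma 3.58.1 (trend = TRUE) in R 4.3.3 and the package data.table (1.17.8). Calls used a Benjamini-Hochberg adjusted p under 0.05. Level comparisons averaged the contrast between arms over times. Rhythms were tested as the joint F test of the sine and cosine terms of a 24 h period in each arm, and differences as the joint F test of the differences of those terms. An amplitude is the fitted distance from mean to peak on the log2 scale. The fibroblasts with 2 times were tested for the CT24 to CT12 change in each arm and for the difference of these changes. Means ± SD in the text are of the deposited TPM or FPKM without rescaling.

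The tests, the alternatives, the rule for named genes and 42 gene lists with 996 entries were chosen before the data were examined. Of the list entries, 964 matched a name in the KO experiment directly and 10 through synonyms, 963 matched in the DZnep fibroblasts and 981 in the SCN. Lists with 5 or more tested members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The lists covered the clock, the methionine cycle, chromatin and stress pathways, the cell cycle, metabolism and markers of other cell types. Markers of epithelial cells and mitochondrially encoded mRNAs had fewer than 5 tested members in each experiment and were not tested with camera. The rule named Ahcy, up to 8 higher and 8 lower called genes with the largest log2 change, a mean of 5 or more, the same sign at every time and a name that is not a predicted gene model. It also named up to 4 called members per list described with the smallest p, the clock list, and up to 6 genes each with the largest control amplitude or time change and the largest difference of terms. A few genes that the rule would name are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Gene locations are those of GENCODE vM21 on GRCm38, the same build as mm10.

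Alternatives were a pseudocount of 0.1, values as deposited, quantile normalization, no filter, a filter on a mean of 5 or more, a log2 change of 1 or more, any difference among times in place of the cosine shape, a linear time trend, the replicate number as a block, and leaving out each library in turn. After the data had been seen, fits were added without libraries with high Malat1, without CT12, without CT20 and without an SCN library with high immune genes. The tests were run on simulated data first, with 50 genes changed per size. The level test recovered 88%, 32% and 88% of genes changed by 0.25 on the log2 scale in the KO, DZnep fibroblast and SCN settings, and 94%, 100% and 100% of genes changed by 1. The test of a rhythm difference recovered 74% of amplitudes of 0.25 among 13603 genes in the KO setting and 44% among 13312 genes in the SCN setting. The test of a time difference recovered 38% of differences of 0.5 among 10896 genes in the DZnep fibroblasts. The simulated noise was the spread within groups, with no time change of another shape than the cosine. The rhythm tests on the real libraries may therefore recover fewer genes.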

Results

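RNA sequencing was done on 79 mouse libraries in 3 experiments around adenosylhomocysteinase (AHCY), the enzyme that breaks down S-adenosylhomocysteine, the product and inhibitor of methyl transfer reactions. The experiments ask how this enzyme bears on the circadian clock. In the first, wild-type (WT) mouse embryonic fibroblasts and fibroblasts with Ahcy knocked out by CRISPR-Cas9 (KO) were collected at 6 circadian times (CT), from CT12 to CT32 in steps of 4 h, with 3 libraries per group. In the second, fibroblasts received the solvent dimethyl sulfoxide (DMSO) or 3-deazaneplanocin A (DZnep), an AHCY inhibitor, and were collected at CT12 and CT24 with 3 libraries per group. In the third, the suprachiasmatic nucleus (SCN), the pacemaker of the hypothalamus, was taken at CT3, CT9, CT15 and CT21 from mice infused with saline or DZnep, with 4 libraries per group and 3 for saline at CT21. The labels call the libraries of a group biological replicates. Genes at 1 or more numbered 11937 to 12735 per library in the KO experiment, 10388 to 10696 in the DZnep fibroblasts and 12304 to 13117 in the SCN. Read depth is unknown.

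Ahcy, on the minus strand of chromosome 2 from 155059310 to 155074497, was almost absent from KO fibroblasts. It stood at 176 ± 24.7 TPM in WT and 3.16 ± 0.672 TPM in KO (SD, n = 18 each), with ranges of 131 to 214 and 2.21 to 4.74 TPM, so each library matched its label. The log2 change was -5.60 (SE 0.044, adjusted p = 3.3e-36, limma). DZnep acts on the enzyme, and over all libraries the Ahcy mRNA passed no test with it. Its level was 30.6 ± 9.10 FPKM with DMSO and 25.1 ± 5.63 FPKM with DZnep in fibroblasts (n = 6 each, adjusted p = 0.12), and 9.37 ± 1.27 FPKM with saline (n = 15) and 9.43 ± 0.680 FPKM with DZnep (n = 16) in the SCN (adjusted p = 0.996). The fibroblast result rested on replicate 2 of DMSO at CT24, which held 13.7 FPKM of Ahcy and a high level of the nuclear RNA Malat1. Without it, a fit chosen after the data were seen, DMSO stood at 33.9 ± 4.32 FPKM (n = 5) and Ahcy fell with DZnep (log2 change -0.46, adjusted p = 1.0e-05, limma).

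KO fibroblasts differed from WT in most of the genes measured. Among the genes with the largest rises were the surface protein gene Thy1 (3.11 ± 0.485 TPM in WT, 783 ± 113 TPM in KO, n = 18 each, log2 change 7.38), the membrane protein gene Adam23 (0.255 ± 0.0632 to 94.5 ± 9.56 TPM), Psmb8, a subunit of the immunoproteasome (0.302 ± 0.189 to 66.7 ± 4.17 TPM), and podoplanin, Pdpn (1.87 ± 0.36 to 126 ± 18.1 TPM). Ecscr rose by 5.35, H2-q6 by 5.35 and Fam5c by 5.89 on the log2 scale. Mir5103 rose by 8.37, though a microRNA gene this short is poorly measured by such libraries. Of the named genes that fell, serum amyloid Saa3 went from 3209 ± 1425 to 1.37 ± 2.48 TPM (log2 change -10.78), matrix Gla protein Mgp from 3462 ± 544 to 3.90 ± 2.27 TPM (-9.77), haptoglobin Hp from 631 ± 172 to 0.311 ± 0.561 TPM (-9.05) and lipocalin Lcn2 from 261 ± 62.1 to 0.151 ± 0.187 TPM (-7.93). The growth factor gene Igf2 (-7.71), its binding protein gene Igfbp4 (-7.43) and the protease inhibitor gene Serpina3n (-7.11) fell with them, as did the noncoding RNA Xist (-7.39). In all of these the 18 KO libraries lay apart from the 18 WT libraries. Of 13603 genes tested, 5791 rose and 6396 fell, which is 89.6% of them, with a median size of 0.50 on the log2 scale among called genes, and 984 and 1471 of them changed at least 2-fold. Rescaling moved the KO libraries against the WT libraries by 0.22 on the log2 scale, and with the values as deposited 7280 genes rose and 4857 fell. Without the CT20 libraries, a fit chosen after the data were seen, 5730 rose and 6263 fell. Markers of the sex chromosomes separated the arms as well. Xist, the RNA that silences the inactive X chromosome, was 176 ± 24.0 TPM in WT and 0.140 ± 0.0619 TPM in KO, while the Y-linked Ddx3y, chosen after its values were seen, was 0.307 ± 0.0937 TPM in WT and 18.4 ± 0.994 TPM in KO (n = 18 each). For any gene of this comparison, rhythms included, a difference between lines cannot be told from the loss of AHCY.

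Targets of the tumour suppressor p53 fell in KO fibroblasts, with 21 of 24 tested members lower, 2 higher and 1 not passing, the same counts when adjusted over the list alone (camera adjusted p = 3.5e-05, and adjusted p = 0.00087 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell from 106 ± 9.92 to 6.50 ± 1.45 TPM, the cyclin Ccng1 from 296 ± 15.2 to 40.6 ± 2.28 TPM, while the receptor gene Eda2r and the junction protein gene Perp fell with log2 changes of -4.75 and -3.42. This was the only list of the 34 tested whose call held with an estimated correlation. Genes of the cell cycle rose. For mitosis 24 of 30 rose and 6 fell (camera adjusted p = 0.00087, adjusted p = 0.320 with an estimated correlation), led by Tpx2, a spindle factor (72.9 ± 9.77 to 199 ± 7.31 TPM). For DNA replication 21 rose, 5 fell and 4 did not pass (0.0077, adjusted p = 0.411 with an estimated correlation), with the cyclin gene Ccne1 at 25.9 ± 7.12 and 70.8 ± 7.20 TPM and the clamp gene Pcna at 327 ± 88.3 and 670 ± 45.6 TPM. All 30 ribosomal protein genes fell (5.4e-07, adjusted p = 0.294 with an estimated correlation), such as Rpl3 from 3101 ± 228 to 1887 ± 90.2 TPM. Their count was 28 with the values as deposited and 20 after quantile normalization.

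Metabolic lists moved apart in KO fibroblasts. Of 23 cholesterol synthesis genes 21 rose and 2 fell (camera adjusted p = 3.5e-05, adjusted p = 0.233 with an estimated correlation), among them Hsd17b7 (log2 change 2.06), Idi1 (1.76) and Nsdhl (1.73). Of 27 genes of the ATF4 response to amino acid shortage 23 rose, 3 fell and 1 did not pass (6.2e-05, adjusted p = 0.204 with an estimated correlation). Atf4 itself went from 270 ± 29.2 to 610 ± 22.5 TPM, and the aminoacyl-tRNA synthetase gene Cars and the serine synthesis gene Psph each rose by 1.27, while the lipoprotein receptor gene Vldlr fell by 2.39. Of 27 glycolysis and hypoxia genes 22 fell, 4 rose and 1 did not pass (0.00032, adjusted p = 0.233 with an estimated correlation), such as Pfkl (-2.50), Bnip3 (-2.31), Pdk1 (-2.01) and P4ha1 (-1.73). The Hox genes, which hold positional identity, fell in 22 of 29 cases and rose in 7 (0.0012, adjusted p = 0.204 with an estimated correlation). Hoxc10 went from 46.1 ± 3.95 to 0.125 ± 0.0954 TPM and Hoxc8 from 36.4 ± 3.12 to 0.194 ± 0.0867 TPM. All 8 tested markers of meningeal fibroblasts fell, including the collagen gene Col3a1 (593 ± 134 TPM in WT, log2 change -5.56) and Ogn (144 ± 76.8 to 2.17 ± 1.02 TPM) (0.00011, adjusted p = 0.204 with an estimated correlation). Of 6 endothelial and mural markers 5 fell and 1 rose (0.042, adjusted p = 0.204 with an estimated correlation), led by Ly6c1 (-5.39), and without the CT20 libraries 4 of 5 fell and the adjusted p was 0.0704. Counts adjusted over each of these lists alone were the same.

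Most clock genes cycled in WT fibroblasts, with lower amplitudes in KO fibroblasts. Per2, a repressor of the clock on chromosome 1 from 91415982 to 91459324, ran from 0.242 ± 0.0341 TPM at CT12 to 6.6 ± 0.455 TPM at CT24 in WT, and stood at 0.503 ± 0.0946 and 0.362 ± 0.0464 TPM at these times in KO (n = 3 per group). The output factor Dbp reached 15.8 ± 1.75 TPM at CT20 in WT against 1.14 ± 0.160 TPM in KO, and the repressor Nr1d1 reached 32.3 ± 1.04 TPM against 9.52 ± 0.573 TPM at the same time. The 3 WT libraries of CT20 also held skeletal muscle mRNAs, and the counts without CT20 are given below. The activator Arntl dipped to 5.94 ± 0.116 TPM at CT24 in WT and was 19.6 ± 1.06 TPM in KO. The fitted amplitude went from 1.56 to 0.16 for Dbp (adjusted p of the difference 6.1e-06), from 1.28 to 0.093 for Per2 (5.7e-13), from 1.10 to 0.20 for Cry1 (2.6e-10), from 1.04 to 0.15 for Nr1d1 (3.4e-07) and from 0.75 to 0.050 for Arntl (3.5e-07). Of 22 clock genes tested 18 were rhythmic in WT, 6 in KO (7 adjusted over the list alone) and 16 differed between the arms (17 adjusted over the list alone). The 6 in KO were Cry1, Csnk1d, Bhlhe41, Tef, Nr1d2 and Nfil3, and Tef kept an amplitude of 0.45 there against 1.26 in WT. All 6 were rhythmic in WT too, with other fitted peaks. The peak in KO minus WT was 4.58 h for Tef, 4.96 h for Cry1 and 6.04 h for Nr1d2. It was 7.17 h for Bhlhe41, 9.96 h for Nfil3 and -7.22 h for Csnk1d. In KO Nfil3 went from 35.6 ± 1.40 TPM at CT12 to 25.9 ± 0.237 TPM at CT32, so a drift cannot be told from a rhythm there. With any difference among times in place of the cosine shape, 15 of the 22 changed in KO. Over all 22 the median amplitude was 0.47 in WT and 0.13 in KO, and 19 had the lower value in KO. The mean level of the list also shifted, with 16 members lower and 6 higher in KO (camera adjusted p = 0.036, adjusted p = 0.204 with an estimated correlation), and camera's adjusted p was 0.053 without the CT20 libraries. Hlf fell from 17.3 ± 5.52 to 0.644 ± 0.258 TPM and Nr1d2 from 29.3 ± 18.1 to 6.69 ± 1.30 TPM over all times. The count of 6 in KO was 3 without replicate 2 of KO at CT12, 3 without replicate 2 of KO at CT28, and 3 after quantile normalization.

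**Figure D1:**
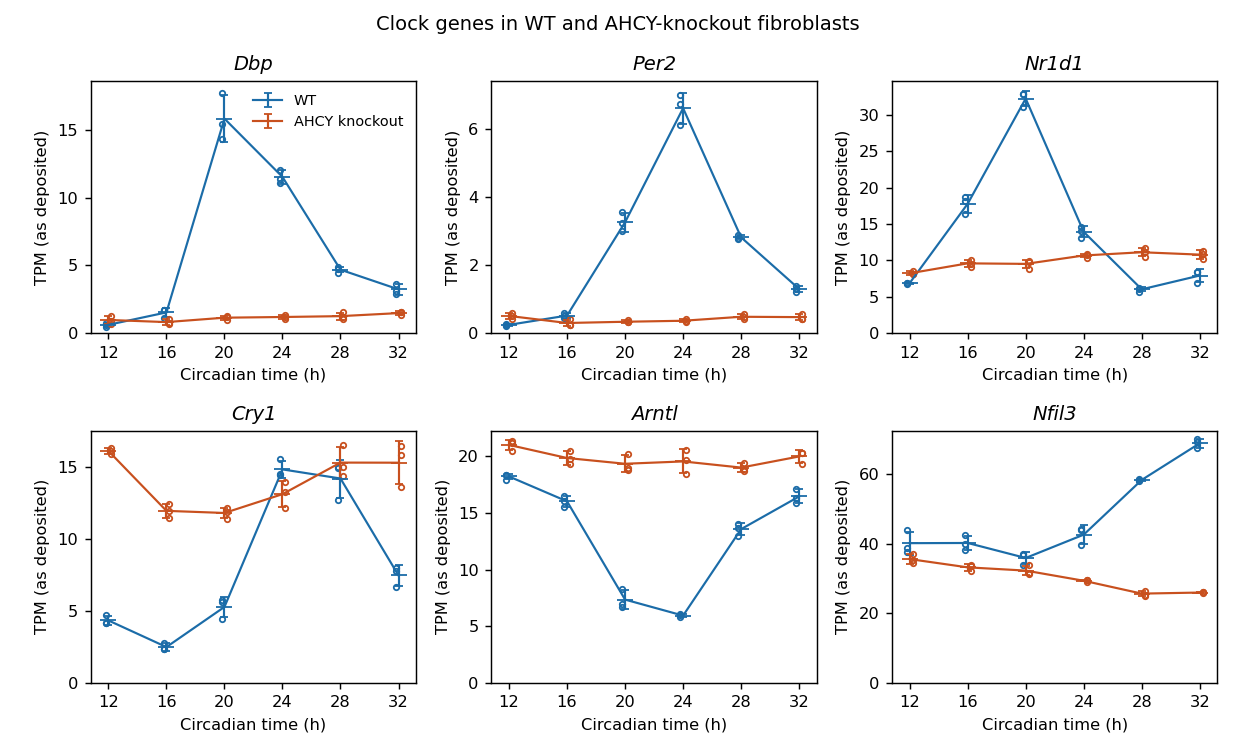
Values of clock genes in TPM against circadian time in h for WT and KO fibroblasts, with a point per library and lines through the means of 3 libraries with SD bars. Per2 reached 6.6 TPM at CT24 in WT and 0.362 TPM in KO.

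Across all genes, WT fibroblasts had 4970 rhythmic genes and KO fibroblasts 1345, and 1970 genes had different 24 h terms, of which 1300 had the lower amplitude in KO and 670 the higher. The 480 genes rhythmic in both arms were about as many as the 491 that independent lists would give. The named genes with the largest amplitudes were the microRNA genes Mir709 (3.68), Mir143 (3.57), Mir668 (3.32), Mir145 (3.18), Mir26b (3.10) and Mir369 (2.81), which are too short to be measured well. Mir453 had the largest difference of terms (5.10). Tnnc2 and Mylpf, genes of skeletal muscle fibres, differed too, with WT peaks at 19.4 h and 20.2 h. They belong to a set of muscle genes high in the 3 WT libraries at CT20, chosen after their values were seen. Ckm, muscle creatine kinase, was 50.6 ± 10.7 TPM there (n = 3) and at most 0.066 TPM at other WT times, with Acta1 at 80.4 ± 12.0, Tnnt3 at 77.9 ± 16.1, Myl1 at 55.9 ± 7.03 and the adult fast myosin Myh4 at 43.4 ± 10.7 TPM, while the embryonic myosin Myh3 was 0.0143 ± 0.0248 TPM. Without the CT20 libraries of both arms the counts were 6242, 1836 and 2498, and 17, 6 and 17 for the clock list. The times cover less than a full day. With a linear time trend in each arm, which takes out a steady drift, the counts were 4228, 907 and 2203, and 17, 5 and 17 for the clock list. With any difference among times in place of the cosine shape the counts were 9454, 5813 and 7103. Without 6 libraries in which the nuclear RNA Malat1 was over 2 times the median of its arm, the KO count was 850 and the difference 1306.

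DZnep changed many genes in fibroblasts. Thrombospondin Thbs1, a matrix glycoprotein, rose from 25.1 ± 2.30 FPKM with DMSO to 657 ± 72.2 FPKM with DZnep (n = 6 each, log2 change 4.6), the collagen gene Col10a1 from 0.448 ± 0.163 to 27 ± 4.89 FPKM, Perp from 3.46 ± 0.218 to 40.5 ± 2.46 FPKM and the growth factor gene Ctgf from 7.51 ± 2.1 to 81.4 ± 56.4 FPKM. The water channel gene Aqp1 (2.73), cyclooxygenase Ptgs2 (2.50), Anxa8 (2.42) and the transcriptional inhibitor Id1 (2.33) rose as well. The matrix genes Matn2 (23.6 ± 4.95 to 1.75 ± 0.230 FPKM), Col3a1 (250 ± 23.7 to 42.6 ± 9.90 FPKM) and Col5a3 (log2 change -2.73) fell, as did Ifitm1 (-2.98), Nrep (-2.93), Angptl2 (-2.58), the opioid peptide gene Penk (-2.42) and Serpinf1 (-2.34). Of 10896 genes tested 3610 rose and 3567 fell, 243 and 326 of them at least 2-fold. All libraries of each of these named genes lay apart between the arms.

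The p53 targets rose with DZnep, opposite to their direction in KO fibroblasts. Of 24 tested, 21 rose, 2 fell and 1 did not pass (22 and 2 adjusted over the list alone, camera adjusted p = 5.8e-09, and adjusted p = 0.0032 with an estimated correlation). Mdm2, the ligase that degrades p53, went from 35.9 ± 3.63 to 157 ± 5.06 FPKM, the death factor Pmaip1 from 6.29 ± 0.246 to 29.9 ± 0.754 FPKM and Btg2 from 10.6 ± 0.811 to 42.5 ± 5.03 FPKM. DNA replication genes rose in 27 of 30 cases with 3 not passing (7.8e-08, adjusted p = 0.431 with an estimated correlation), such as Cdc6 (5.50 ± 2.96 to 14.0 ± 2.36 FPKM) and Rrm2 (log2 change 1.31). Mitosis genes rose in 23 of 30 cases with 7 not passing (3.1e-05, adjusted p = 0.261 with an estimated correlation), including Tpx2 (0.64) and Foxm1 (0.67). Immediate early genes rose in 14 of 19 cases, fell in 2 and did not pass in 3 (0.00046, adjusted p = 0.106 with an estimated correlation), with Klf4 at 1.99, Egr1 at 1.28 and the neuronal factor Npas4 at -1.40. All 30 ribosomal protein genes fell (1.5e-06, adjusted p = 0.501 with an estimated correlation), for example Rpl5 from 278 ± 52.3 to 155 ± 18.1 FPKM. Their count was 28 with the values as deposited and 24 after quantile normalization. Glycolysis and hypoxia genes fell in 18 of 25 cases, rose in 3 and did not pass in 4 (0.00011, adjusted p = 0.374 with an estimated correlation), with Bnip3 at -1.37 and Pdk1 at -1.21. Hox genes fell in 14 of 23 cases, rose in 1 and did not pass in 8 (0.0074, adjusted p = 0.50 with an estimated correlation), with Hoxb9 at -1.05. Cholesterol synthesis genes fell in 14 of 22 cases, rose in 1 and did not pass in 7 (0.044, adjusted p = 0.431 with an estimated correlation, and 0.052 with the values as deposited), led by the regulator Srebf2 (-0.75). Apart from the p53 targets, counts adjusted over each of these lists alone were the same.

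Of the 21 clock genes tested, 6 had a lower log2 change between CT12 and CT24 with DZnep than with DMSO. Dbp rose from 1.06 ± 0.206 to 11.5 ± 1.81 FPKM with DMSO and from 0.927 ± 0.0575 to 3.23 ± 0.295 FPKM with DZnep (n = 3 per group, difference of log2 changes -1.50, adjusted p = 0.00025). Per2 reached 2.58 ± 0.539 FPKM at CT24 with DMSO and 1.18 ± 0.0242 FPKM with DZnep (-0.88, adjusted p = 0.0081). The repressor Cry1 rose from 1.62 ± 0.269 to 3.69 ± 0.207 FPKM with DMSO and fell from 5.24 ± 0.211 to 3.14 ± 0.237 FPKM with DZnep (-1.43, adjusted p = 6.0e-05). Per3 (-1.21), Tef (-0.98) and Nfil3 (-0.51) also had a lower change with DZnep. Of the list 18 changed with DMSO, 14 with DZnep (17 adjusted over the list alone) and these 6 differed between the arms (10 adjusted over the list alone). Not every member went this way. Nr1d1 changed by 1.79 with DZnep, which was 0.29 more than with DMSO (adjusted p = 0.127, and 0.0356 adjusted over the list alone), Rora by 0.91 and 1.39, Hlf by 1.45 and 1.51, and the change of Nr1d2 differed by -0.032. The clock level over both times rose in 7 members, fell in 9 and did not pass in 5 (camera adjusted p = 0.754).

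**Figure D2:**
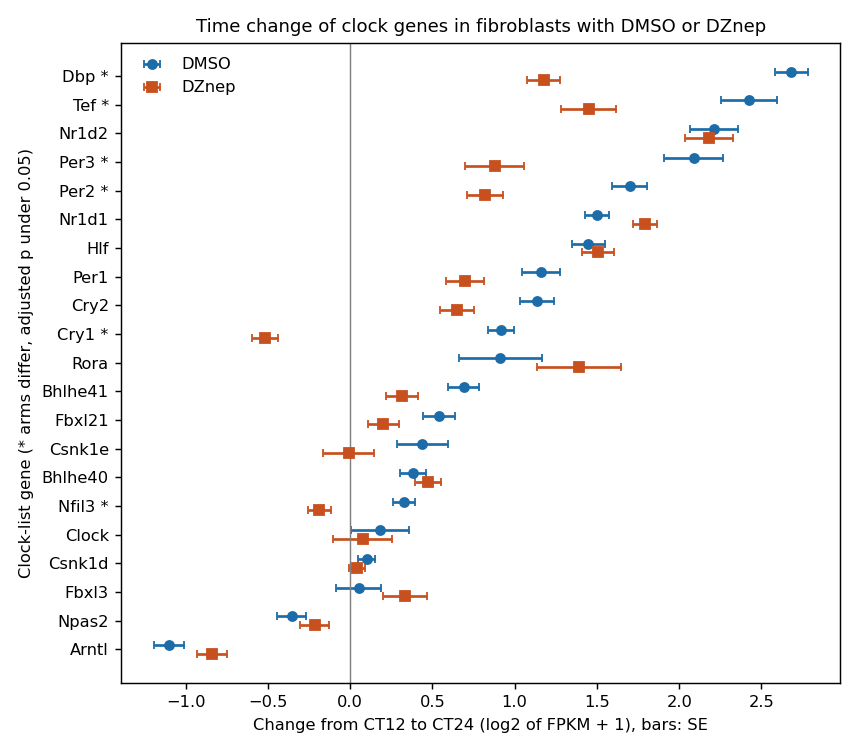
Change of the 21 clock genes from CT12 to CT24 on the log2(FPKM + 1) scale for fibroblasts with DMSO or DZnep, with bars of 1 SE and a star where the arms differed. The stars mark 6 genes.

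Across all genes 5529 changed between CT12 and CT24 with DMSO, 4053 with DZnep and 666 differed between the arms, of which 433 had the smaller change with DZnep. Among the 3065 genes called in both arms 2994 changed in the same direction. The log2 change with DZnep minus that with DMSO was negative for the peptide gene Cck (-1.79, adjusted p = 0.0175), Ctgf (-1.47) and the contractile gene Myl9 (-1.44). It was positive for Serpina3n (1.61) and the growth factor gene Bmp4 (1.36). In size, all of these genes changed more with DZnep. Cck changed by -0.85 with DMSO and -2.63 with DZnep, and Myl9 by 0.39 and -1.05. Serpina3n changed by -0.42 and 1.19, and Bmp4 by 0.48 and 1.85. Ctgf fell in both arms, and further with DZnep. Outside the clock list and among genes with a mean of 5 or more, the largest changes with DMSO were in Dab2ip (2.48), U90926 (-2.21), the retinal dehydrogenase gene Aldh1a1 (2.04), the contractile gene Tagln (-1.92), Ces1a (1.82) and Dctpp1 (-1.80). The count of 666 moved by more than 1.5 times without any of 10 of the 12 libraries. Without replicate 3 of DMSO at CT24 it was 1939. Without replicates 1, 2 and 3 of DMSO at CT12 it was 320, 346 and 395, without those of DZnep at CT12 it was 352, 315 and 437, and without those of DZnep at CT24 it was 327, 339 and 294.

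The effects of the KO and of DZnep in fibroblasts were weakly related across genes. Over 10742 genes tested in both, the log2 changes at CT12 and CT24 had a Pearson correlation of 0.185 (jackknife SE over libraries 0.0112) and a Spearman correlation of 0.235, and genes are not independent replicates. Of 6108 genes called in both 63.0% had the same sign. Both rose for 1832 genes where independent lists would share 1444, and both fell for 2018 genes against 1562. Opposite directions held for 1024 genes against 1435 and for 1234 against 1572. The comparisons share no libraries. Col3a1, Bnip3, Pdk1 and Hoxb9 stood for genes lower with both treatments, while Perp and Mdm2 fell in KO and rose with DZnep.

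In the SCN, DZnep gave many small changes. Etnppl, an astrocyte enzyme of phosphoethanolamine breakdown, rose from 16.4 ± 3.70 FPKM with saline (n = 15) to 42.7 ± 9.15 FPKM with DZnep (n = 16, log2 change 1.32), the matrix gene Fbln5 from 3.67 ± 0.471 to 8.09 ± 1.85 FPKM and Itih3 from 53.7 ± 9.41 to 95.9 ± 10.4 FPKM, and all libraries of these 3 genes lay apart between the arms. Rasd1 (0.74), Igf2 (0.72), Hmgn5 (0.64), the stress factor Nupr1 (0.61) and the repeat-derived RNA Rn4.5s (1.16) rose too. The parathymosin gene Ptms fell from 198 ± 23.5 to 122 ± 19.7 FPKM, and Smim4 (-0.92), Arhgef25 (-0.80), Flywch2 (-0.78), Snhg12 (-0.76), Tmem91 (-0.73), Marcksl1 (-0.70) and Baiap3 (-0.67) fell with it. Of 13312 genes tested 2255 rose and 2433 fell, 3 and 3 of them at least 2-fold. With the values as deposited 2257 rose and 1586 fell. The nuclear RNA Malat1, chosen after its values were seen, was 1060 ± 143 FPKM with saline and 771 ± 112 FPKM with DZnep (-0.49, adjusted p = 0.000195).

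A saline library, replicate 2 of CT09, stood apart with high levels of immune genes, which were chosen after their values were seen. The invariant chain Cd74 was 539 FPKM in it and 7.65 ± 3.20 FPKM in the other 30 SCN libraries, B2m was 620 against 42.2 ± 8.16, the lysozyme Lyz2 296 against 11.5 ± 4.33, the chemokine Ccl5 162 against 0.687 ± 0.623 and Saa3 208 against 0.263 ± 0.760 FPKM. The peptide genes Vip (84.8 against 126 ± 27 FPKM) and Avp (166 against 159 ± 86.0 FPKM), which mark SCN neurons, lay within the range of the others. In this library 277 genes were over 5 times the highest other saline library, and at most 9 were so in any other SCN library within its arm. Without it 2433 genes rose and 2622 fell with DZnep. The interferon list, in which 0 of 24 genes passed (2 at an unadjusted p under 0.05, limma), then had 4 higher and 1 lower of 22 tested.

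Ribosomal protein genes fell in the SCN as in the fibroblasts. With DZnep 28 of 30 were lower and 2 did not pass (camera adjusted p = 1.0e-20, adjusted p = 0.459 with an estimated correlation), such as Rpl3 from 318 ± 30.5 to 212 ± 33.4 FPKM and Rpl5 from 118 ± 13.7 to 86.2 ± 10.3 FPKM. Their count was 26 with the values as deposited and 27 after quantile normalization. Genes of the ATF4 response rose in 16 of 25 cases with 9 not passing (17 adjusted over the list alone, 3.1e-06, adjusted p = 0.459 with an estimated correlation). Atf4 went from 36.2 ± 4.72 to 50.3 ± 7.54 FPKM, the asparagine synthetase gene Asns from 13.4 ± 1.53 to 17.2 ± 2.40 FPKM, and Mars and Slc7a5 rose by 0.38 and 0.35. Cholesterol synthesis genes fell in 16 of 23 cases with 7 not passing (17 adjusted over the list alone, 0.00022, adjusted p = 0.979 with an estimated correlation), among them the regulator Srebf2 (-0.24). Nuclear genes of the respiratory chain rose in 13 of 32 cases, fell in 2 and did not pass in 17 (14 and 2 adjusted over the list alone, 0.0046, adjusted p = 0.979 with an estimated correlation), led by Cox6a1 (77.5 ± 6.08 to 103 ± 9.79 FPKM). Markers of oligodendrocyte precursors fell in 5 of 10 cases, with Pdgfra from 8.13 ± 0.808 to 5.51 ± 0.760 FPKM, and the list passed only with the values as deposited (camera adjusted p = 0.0895 and 0.026, and adjusted p = 0.979 with an estimated correlation over the rescaled values). Glucocorticoid targets rose in 7 of 21 cases, with glutamine synthetase Glul from 181 ± 24.3 to 242 ± 33.2 FPKM and Fkbp5 at 0.28 (0.104), and in 9 of 21 without the saline library with high immune genes (0.0295), while the adjusted p was 0.979 with an estimated correlation over all libraries.

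The SCN clock kept cycling with DZnep and peaked later, as did most other genes rhythmic in both arms. Outside the clock and heat shock lists 88.3% of 806 such genes were later, with a median shift of 1.86 h over all 806. A sampling offset therefore stays open. Of 24 clock genes tested 22 were rhythmic with saline and 20 with DZnep, with median amplitudes of 0.43 and 0.45 over all 24. In the 20 genes rhythmic in both arms the peak was later with DZnep in 20, by a median of 1.45 h and by 0.640 to 2.30 h (permutation p = 0.007, 2-sided, 100000 resamples of treatment within time, a test chosen after the shift was seen). The peak moved from 4.07 to 5.83 h for Nr1d1, from 7.37 to 9.25 h for Dbp, from 6.76 to 9.06 h for Per1 and from 10.3 to 11.7 h for Per2. At CT3 Nr1d1 was 54.8 ± 10.7 FPKM with saline and 40.7 ± 6.53 FPKM with DZnep, and at CT9 it was 35.3 ± 5.24 and 44.5 ± 4.16 FPKM (n = 4 per group). In the test of each gene over all genes only Nr1d1 differed (adjusted p = 0.048), and 8 differed when adjusted over the list alone. Adjusted over all genes, the count of clock genes was 0 with a pseudocount of 0.1, with the values as deposited, with no filter and with the replicate number as a block. It was 4 with a mean of 5 or more and 2 with any difference among times, and it rested on single libraries. It was 6 and 3 without replicates 4 and 3 of DZnep at CT15, and 2 without replicate 2 of saline at CT03, replicate 2 of saline at CT09 or replicate 1 of DZnep at CT03. It was 1 without replicate 3 of saline at CT03, replicate 3 of saline at CT21, replicates 2 and 4 of DZnep at CT03 or replicate 3 of DZnep at CT21, and 0 without any of the other 21, where 10 genes of the full fit had an unadjusted p under 0.05 in limma. The clock list's level rose in 3 members, fell in 4 and did not pass in 17 (camera adjusted p = 0.681), with Per3 at -0.36, and 3 rose and 8 fell without the saline library with high immune genes (0.469).

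**Figure D3:**
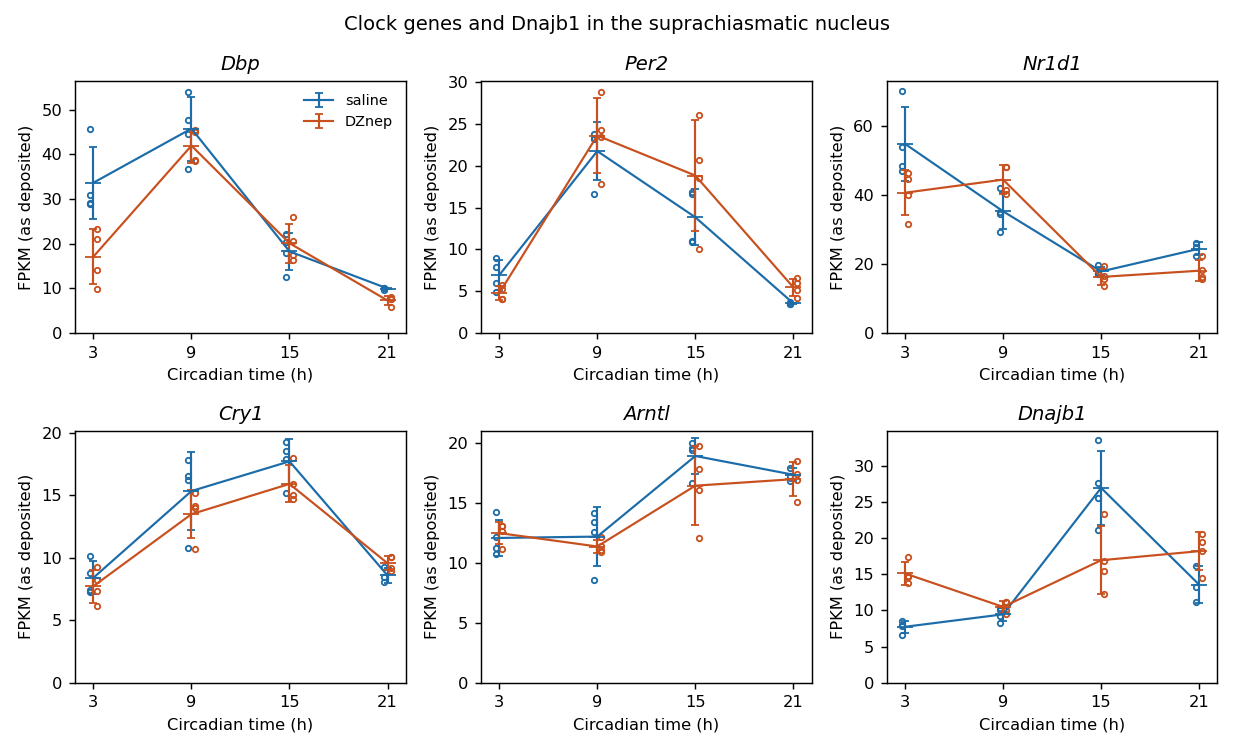
Values of clock genes and Dnajb1 in FPKM against circadian time in h for the SCN with saline or DZnep, with a point per library and lines through the group means with SD bars. Nr1d1 was 54.8 FPKM at CT3 with saline and 40.7 FPKM with DZnep.

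Of 20 heat shock genes, a list singled out after its values were seen, 17 were rhythmic in the SCN with saline and 9 with DZnep. Between the arms 5 differed and 15 did not pass, and 17 differed when adjusted over the list alone. Dnajb1, a co-chaperone, peaked at CT15 with 26.9 ± 5.12 FPKM with saline and stood at 16.9 ± 4.67 FPKM with DZnep (n = 4 each), and its amplitude went from 0.84 to 0.36 (adjusted p = 0.0014). Chordc1 (0.56 to 0.23) and Hsph1 (0.54 to 0.32) differed too, as did the splicing factor genes Srsf5 (0.48 to 0.29) and Tra2a (0.38 to 0.15) and the myelin gene Opalin (0.67 to 0.22). In the 9 heat shock genes rhythmic in both arms the peak was later by a median of 4.43 h, from 3.42 to 6.44 h. Their level rose in 4 of 20 cases, fell in 3 and did not pass in 13 (camera adjusted p = 0.688).

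**Figure D4:**
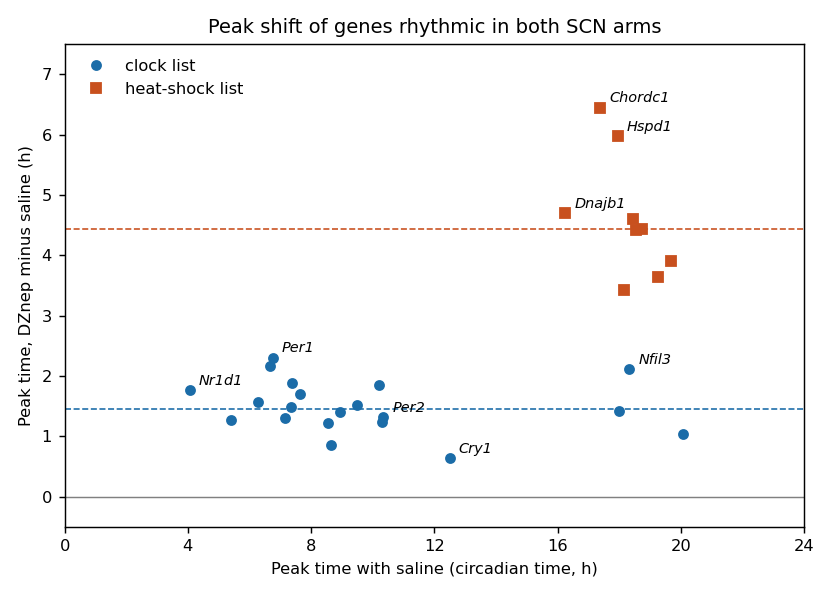
Peak time with DZnep minus saline in h against the peak time with saline, for clock and heat shock genes rhythmic in both SCN arms, with a point per gene and dashed lines at the medians. The medians were 1.45 h for the clock list and 4.43 h for the heat shock list.

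Across all genes 2436 were rhythmic in the SCN with saline, 1356 with DZnep and 41 differed between the arms, 35 with the lower amplitude with DZnep and 6 with the higher. Both arms shared 835 rhythmic genes where independent lists would share 248. Outside the clock list and among genes with a mean of 5 or more, the largest amplitudes with saline were those of the small nucleolar RNA genes Snora34 (3.77) and Snora24 (2.73), which are too short to be measured well, followed by the signalling genes Rasl11b (1.72), Dusp4 (1.70), Rasd1 (1.28) and Rgs16 (1.14). The count of 41 moved with single libraries. It was 114 without the saline library with high immune genes, 68 without replicate 3 of saline at CT03 and 26 without replicate 2 of saline at CT15. Without replicates 1, 2, 3 and 4 of DZnep at CT15 it was 20, 22, 102 and 190. With the values as deposited it was 12, and 1615 genes were rhythmic with saline. Without the library with high immune genes 2669 and 1740 genes were rhythmic, the clock peaks were later by a median of 1.46 h, and 8 heat shock genes differed.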

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

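The tests of sex-linked genes, of autosomal genes, of p53 targets, of short abundant mRNAs, of permuted treatment and of a shared sampling offset were chosen after the result they bear on had been seen.

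KO and WT fibroblasts differed in 12187 of 13603 tested genes. Of the tested autosomal genes 89.8% were called, as were 89.2% of those on the X chromosome. With 12319 of 12740 located genes on autosomes, the autosomal share could hardly differ from that of all genes. It shows only that the change was not confined to the sex chromosomes. With the values as deposited 89.2% of all tested genes were called, which argues against the joint rescaling as the source. In 36 of 36 libraries Xist and 4 Y-linked genes placed the arms on opposite sides. Xist was at least 135 TPM in WT and at most 0.273 TPM in KO. The 4 Y-linked genes were at most 0.559 TPM in WT and at least 8.01 TPM in KO. These values argue against KO cells derived from the WT cells measured here, and go with lines of different sex. All 20 p53 targets that rose with DZnep and were tested in KO were lower in KO, but 21 of 24 p53 targets were lower there anyway, so this leaves a loss of p53 activity in the KO line undecided. The p53 gene Trp53 was 180 ± 24.1 TPM in WT and 269 ± 17.2 TPM in KO. Cdkn2a was 79.0 ± 13.8 and 460 ± 43.8 TPM (n = 18 each), both genes chosen after their values were seen. The arms confound any difference between lines with the loss of AHCY, and both stay open for any gene of that comparison.

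Ribosomal protein mRNAs were lower in all 3 comparisons, though the call of the list was lost with an estimated correlation (camera adjusted p = 0.294, 0.501 and 0.459) and 20, 24 and 27 of 30 members were lower after quantile normalization. After a trend with gene length had been removed from every library, 30, 30 and 27 of 30 members stayed lower in KO fibroblasts, DZnep fibroblasts and DZnep SCN, with median log2 changes of -0.74, -0.85 and -0.29 before and -0.67, -0.70 and -0.28 after. Nuclear genes of the respiratory chain, also short, had medians of -0.041, -0.16 and 0.075. This argues against a general lower yield of short mRNAs in KO fibroblasts and the SCN. In the DZnep fibroblasts 13 of 32 were lower and 1 higher, so a lower yield stays open there. The lists were not matched, with median lengths of 1661 and 1139.5 bases for respiratory and ribosomal genes. A loss graded by length or abundance therefore stays open. A biological response of these mRNAs to less AHCY activity was not tested. Every comparison sets separately made tables beside each other, and a difference in how the tables were made stays open.

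Clock genes peaked later with DZnep in the SCN. Chance assignment of libraries to treatment is argued against by the permutation p of 0.007, and a single library by the median shift of at least 1.17 h with any 1 library left out. A sampling offset stays open for the clock genes, since 88.3% of the 806 genes rhythmic in both arms outside the clock and heat shock lists were later too, with a median shift of 1.86 h, 0.413 h more than the clock list (jackknife SE over libraries 0.258 h). The 9 heat shock genes were later by a median of 4.43 h, 2.98 h more than the clock list (jackknife SE 0.818 h). Their list was singled out after its values were seen, and the SE does not cover that choice. The larger shift therefore cannot decide on an offset for them. A biological delay of the clock with DZnep was not tested apart from an offset.

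Differences between arms in the same test were found for 1970 genes in the 24 h terms of KO and WT fibroblasts, for 666 genes in the change from CT12 to CT24 with DZnep and DMSO, and for 41 genes in the 24 h terms of the SCN. In the SCN, 84 combinations of a measure and a group of 4 libraries were searched for a library apart from the others, and 6 of them held one. Chance flags about 1 in 20 groups. Saline replicate 2 of CT09, the library with high immune genes, had 13117 genes at 1 or more against 12444 to 12527 in its group, and Per2 at 16.6 FPKM against 23.2 to 23.8 FPKM. Saline replicate 3 of CT15 had a size factor of 0.987 against 1.05 to 1.06. DZnep replicate 2 of CT03 had a size factor of 1.09 against 0.936 to 0.948. Nr1d1 was 19.6 FPKM in saline replicate 1 of CT15 against 17.2 to 17.4 FPKM. Dbp was 45.6 FPKM in saline replicate 4 of CT03 against 28.9 to 31 FPKM.

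Other splits of the same libraries into groups of the same sizes, 100 with the real one, were counted for each result. Chance could be excluded for the KO level, where 1 split gave as many genes higher (5791, highest other 4723) and 1 as many lower (6396, highest other 4723), and for DZnep in fibroblasts with 1 (3610, highest other 1641) and 1 (3567, highest other 1641). It could be excluded for rhythms in KO with 1 (1345, highest other 5). For rhythms in WT only 1 split, the real one, reached 4970 genes, but another gave 4840. That margin is small, so no conclusion on chance is drawn for WT rhythms. The rhythm difference between KO and WT was reached by 2 splits (1970, highest other 6975). In the SCN chance could be excluded with 1 for genes higher (2255, highest other 384) and 1 for genes lower (2433, highest other 384). The same held there with 1 for saline rhythms (2436, highest other 567) and 1 for DZnep rhythms (1356, highest other 370). The rhythm difference in the SCN was reached by 4 splits (41, highest other 343). For the time difference with DZnep in fibroblasts 8 splits gave as many genes (666, highest other 7177), so chance was not excluded. Splits that call several times the real count point to a structure of the samples, since exchanging arms at 1 time turns the treatment effect into a difference of time changes. In other splits the treatment effect adds to the spread. The splits therefore cannot decide on chance for the rhythm and time differences between arms. Splits of libraries also say nothing on a chance difference between fibroblast lines. The 10 splits for the time change in each fibroblast arm are too few for a share under 0.05, with 1 as large for DMSO (5529, highest other 1) and 1 for DZnep (4053, highest other 1).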

How the results depend on the processing

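The fits without libraries with high Malat1, without CT12, without CT20 and without the library with high immune genes, and all alternatives of the clock list counts, were chosen after the data had been seen. The 102 alternative log2 changes per experiment for named genes kept their label. Apart from Ahcy these genes were named for being called with the largest changes, so they could hardly lose it. The leave-one-out label used the highest adjusted p of those fits, so a call gained without 1 library could hardly register. A call still changed in 1 fit that this count leaves out. Ahcy in the DZnep fibroblasts passed without the library with high Malat1 (log2 change -0.46, adjusted p = 1.0e-05, limma). Of the counts, 260 of 273 in KO, 111 of 133 in the DZnep fibroblasts and 198 of 223 in the SCN kept their label, within 1.5 times. Of 29 correlations 25 kept theirs, which means within 1 jackknife SE of the main value. That SE is built from the 24 fits without 1 library, so those fits could hardly lose the label. The 4 correlations that moved came from other settings. The exceptions follow, and where the alternative does not itself test fewer genes or ask for more, the cause was not tested. Asking for a log2 change of 1 or more left 984 higher and 1471 lower genes in KO, 243, 326, 239, 136 and 54 genes in the DZnep fibroblasts (higher, lower, DMSO time, DZnep time, difference) with 10, 6 and 3 clock genes, and 3 and 3 in the SCN. Any difference among times gave 9454, 5813 and 7103 genes in the KO experiment (WT, KO, difference) with 15 clock genes in KO, and 80 genes and 2 clock genes with a difference in the SCN. A mean of 5 or more left 11 rhythmic clock genes in WT, 9, 8 and 2 clock genes in the DZnep fibroblasts, and in the SCN 1615 lower genes, 120 with a rhythm difference and 4 such clock genes. Without high Malat1 the KO rhythm had 850 genes and the difference 1306. Clock genes rhythmic in KO were 3 after quantile normalization and at least 3 leave-one-out. As deposited, the SCN had 1586 lower genes, 1615 rhythmic with saline, 12 with a difference and 0 such clock genes. SCN clock genes with a difference were also 0 with a pseudocount of 0.1 and with no filter, 2 without the library with high immune genes, and 0 to 6 leave-one-out. Leaving out 1 library gave 294 to 1939 genes for the DZnep time difference and 20 to 190 for the SCN rhythm difference. The KO and DZnep correlation was 0.159 with a pseudocount of 0.1, 0.167 after quantile normalization, 0.222 with a mean of 5 or more and 0.231 over all 6 KO times. Called lists were 1, 1 and 0 with an estimated correlation in KO, DZnep fibroblasts and SCN (7, 4 and 3 at an unadjusted p under 0.05, camera), and 17 in KO as deposited. A linear time trend gave 4228, 907 and 2203 genes, and leaving out CT12 gave 5274, 1627 and 2055. Replicate numbers gave no clear pairing over all libraries, as 5 of 18, 3 of 6 and 1 of 15 pairs correlated over 0.1 in KO, DZnep fibroblasts and SCN. Yet high Malat1 fell mostly in replicate 2, at CT16, CT24 and CT32 in WT, CT24 and CT32 in KO and CT24 with DMSO. The other such library was replicate 3 of KO at CT16. A factor shared by libraries of the same replicate number is therefore not excluded. With the number as a replicate block the counts were 5796, 6418, 4706, 1227 and 1766 in KO, 3590, 3555, 5438, 3982 and 537 in DZnep fibroblasts, and 2207, 2384, 2284, 1253 and 40 in the SCN, with 0 clock genes with a difference there. Depth is unknown and sets no limit that can be given.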

Other observations

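The comparisons across experiments and the muscle and immune genes in this part were chosen after their values had been seen, while the gene lists were fixed beforehand.

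Methionine cycle genes moved both ways and their list passed in no comparison. In KO fibroblasts 14 of 24 rose, 9 fell and 1 did not pass (camera adjusted p = 0.188), and the AHCY relatives Ahcyl2 (12.9 ± 1.29 to 45.2 ± 2.81 TPM) and Ahcyl1 (135 ± 8.74 to 271 ± 16.7 TPM) rose with the folate enzyme gene Mthfd2 (43.0 ± 10.7 to 114 ± 11.5 TPM). With DZnep 11 of 25 rose, 7 fell and 7 did not pass in fibroblasts (0.446), with Shmt1 at 0.99, and 8 of 24 rose, 3 fell and 13 did not pass in the SCN (0.234), with Cbs, the enzyme that takes homocysteine out of the cycle, from 6.76 ± 1.28 to 9.93 ± 1.29 FPKM. The imprinted noncoding RNA Meg3 was lower in each comparison, from 242 ± 35.1 to 92.0 ± 13.8 TPM in KO (n = 18 each), from 34.5 ± 13.7 to 12.2 ± 1.57 FPKM with DZnep in fibroblasts (n = 6 each) and from 176 ± 26.0 to 119 ± 26.4 FPKM in the SCN (n = 15 and 16). Imprinted genes as a list rose and fell in 6 and 13 of 23 cases in KO (0.160), 3 and 13 of 21 with DZnep in fibroblasts (0.084) and 10 and 10 of 27 in the SCN (0.681), with Slc38a4 at -5.43, Peg3 at -4.67 and Dlk1 at -5.06 in KO. Interferon genes rose in 14 of 23 cases and fell in 5 in KO (0.062), such as Ifi204 (2.56 ± 0.516 to 29.5 ± 2.49 TPM) and Bst2 (15.1 ± 3.97 to 76.5 ± 6.13 TPM), and in 8 and 7 of 18 cases with DZnep in fibroblasts (0.575).

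Chromatin lists passed in no comparison. Genes of Polycomb repression and its demethylases rose and fell in 12 and 10 of 22 cases in KO (0.680), 8 and 11 of 21 with DZnep in fibroblasts (0.446) and 3 and 6 of 20 in the SCN (0.773). The histone methyltransferase gene Ezh2 was 61.2 ± 8.82 TPM in WT and 147 ± 9.47 TPM in KO, 23.0 ± 4.84 and 22.6 ± 5.32 FPKM with DMSO and DZnep, and 3.24 ± 0.428 and 4.14 ± 0.346 FPKM with saline and DZnep. Genes for H3 lysine 4 methylation rose and fell in 8 and 5 of 16, 4 and 4 of 13 and 1 and 6 of 17 cases (0.456, 0.860 and 0.664). Developmental regulators held by Polycomb rose and fell in 18 and 15 of 35, 7 and 9 of 23 and 2 and 1 of 21 cases (0.628, 0.860 and 0.824). Germline genes rose in 3 of 5 and fell in 2 of 5 cases in KO (0.529), with Ddx4 from 0.334 ± 0.0894 to 7.34 ± 3.73 TPM.

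Among the other fibroblast lists, matrix genes rose and fell in 12 and 23 of 36 cases in KO (0.054) and 8 and 17 of 34 with DZnep (0.147), with the crosslinking enzyme gene Lox from 1618 ± 371 to 66.0 ± 10.5 TPM in KO. Contractile genes did so in 9 and 5 of 14 and 6 and 2 of 13 cases (0.175 and 0.281), glucocorticoid targets in 6 and 15 of 22 and 6 and 8 of 19 (0.113 and 0.860), unfolded protein genes in 6 and 12 of 19 and 10 and 3 of 19 (0.192 and 0.071), heat shock genes in 12 and 7 of 20 and 6 and 5 of 20 (0.733 and 0.415) and NRF2 genes in 12 and 8 of 22 and 8 and 6 of 22 (0.529 and 0.606). Respiratory chain genes did so in 15 and 17 of 32 and 1 and 13 of 32 (0.993 and 0.174), immediate early genes in 5 and 15 of 20 in KO (0.088), and ATF4 genes in 12 and 3 of 27 with DZnep (0.071). For markers of other cell types the counts in KO were 3 and 4 of 8 for adipocytes (0.951), 0 and 7 of 8 for skeletal muscle (0.082, with fewer than 5 members tested without the CT20 libraries, where the WT held muscle mRNAs), 0 and 6 of 6 for microglia (0.082), 4 and 5 of 9 for neurons (0.835), 0 and 5 of 5 for oligodendrocytes (0.123), 5 and 3 of 8 for astrocytes (0.720), 5 and 11 of 16 for reactive astrocytes (0.10) and 2 and 5 of 7 for SCN peptides (0.227). With DZnep they were 3 and 3 of 7 for adipocytes (0.954), 1 and 4 of 5 for microglia (0.182), 1 and 4 of 6 for neurons (0.342), 2 and 1 of 5 for astrocytes (0.638), 4 and 9 of 16 for reactive astrocytes (0.267), 1 and 5 of 7 for SCN peptides (0.181) and 2 and 6 of 8 for meninges (0.071). With the values as deposited, some of these lists passed as lower in KO (camera adjusted p). They were matrix genes (0.0037), glucocorticoid targets (0.041), immediate early genes (0.033), and markers of microglia (0.032), reactive astrocytes (0.017) and skeletal muscle (0.025).

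In the SCN the markers of its neurons rose in 5 and fell in 5 of 22 cases (0.664), with Calb2 from 61.4 ± 8.78 to 82.8 ± 12.6 FPKM and Penk from 60.7 ± 9.72 to 44.1 ± 9.39 FPKM, and peptides of neighbouring nuclei rose in 3 of 18 (0.333), with Oxt from 167 ± 64.3 to 224 ± 62.7 FPKM. Oligodendrocyte genes rose and fell in 4 and 2 of 17 cases (0.340), astrocyte genes in 3 and 3 of 16 (0.681), reactive astrocyte genes in 1 and 0 of 15 (0.916), microglia genes in 2 and 1 of 19 (0.773), leukocyte genes in 0 and 1 of 11 (0.664), neuronal genes in 2 and 4 of 23 (0.664), endothelial genes in 1 and 1 of 17 (0.916), meningeal genes in 1 and 1 of 13 (0.688), choroid plexus genes in 1 and 0 of 5 (0.681) and red blood cell genes in 1 and 0 of 6 (0.664). Matrix genes did so in 3 and 5 of 26 (0.830), adipocyte genes in 0 and 1 of 7 (0.688), p53 targets in 5 and 3 of 21 (0.688), DNA replication genes in 2 and 1 of 18 (0.681), unfolded protein genes in 1 and 3 of 19 (0.688), glycolysis and hypoxia genes in 5 and 7 of 27 (0.673), NRF2 genes in 2 and 5 of 21 (0.681) and immediate early genes in 0 and 2 of 17 (0.827). No member passed in limma among 12 ependymal, 11 contractile and 6 mitosis genes, with 1, 1 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.968, 0.681 and 0.895). Adjusted over the list alone, the counts higher and lower differed with DZnep in fibroblasts for clock (9 and 9), glucocorticoid (6 and 9), heat shock (6 and 4), interferon (9 and 7) and respiratory chain genes (1 and 10). In the SCN they differed for methionine cycle (10 and 3), developmental (1 and 0), imprinted (10 and 11), DNA replication (2 and 0), glycolysis and hypoxia (6 and 8), leukocyte (0 and 0), microglia (1 and 1) and endothelial genes (0 and 0). Leaving out the saline library with high immune genes moved some counts over all genes. Reactive astrocyte genes then rose and fell in 4 and 0 of 13 cases (camera adjusted p = 0.413). Leukocyte genes did so in 0 and 3 of 10 (0.483) and NRF2 genes in 5 and 6 of 21 (0.611).

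The WT fibroblast libraries of CT20 held parvalbumin Pvalb at 47.6 ± 7.55 TPM (n = 3), a gene of fast muscle fibres, beside Myh4 and Ckm, while the regulator of muscle precursors Myod1 was 0.0532 ± 0.0232 TPM. The SCN library with high immune genes held the leukocyte marker Ptprc at 15.9 FPKM against 0.652 ± 0.152 FPKM in the other 30 libraries and Aif1 at 36.7 against 2.34 ± 0.723 FPKM.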
